A study of Mus musculus with 10 samples.

How the data were processed

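Tumors of B16F10 cells with or without SSBP4, 5 mice per group by the submitters' design, were harvested on day 15, frozen, thawed and dissociated, and total RNA was extracted with a column kit. The mouse PanCancer immune panel was then counted on the nCounter system, per the labels' protocols. The software, the background step and the settings of the authors' normalization are not given in the sources used here.

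The deposited table holds a signal per gene and library: counts that the authors scaled within each library. From the values, the geometric mean of the 20 housekeeping genes is 966.65 to 966.66 in all 10 libraries, and gene values under 1 were raised to 1. The 6 positive and 8 negative control rows are whole numbers without scaling. Gene values in a library are whole multiples of the value of 1 count, which ranged from 0.5955 to 29.5 normalized counts. Dividing by it gave whole counts for 99.99% of 7482 values above the floor, within 0.02 normalized counts of a whole multiple. The 1 other value, Prf1 in knockout 1, corresponded to 1.68 counts. The recovered counts gave the depth per library, from 11244 to 517427, and served count-based alternatives. A library's background was the mean plus 2 SD of its negative controls. Gene names are those of the table: 756 of 770 matched a current symbol of the GRCm38.p6 annotation, 8 an older symbol and 6 none. No coordinates were used.

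The design written before the data were examined named edgeR for raw counts and limma for normalized values; the deposited values are normalized, so limma was used. Genes with a value of at least 20 in at least 5 libraries were kept, 403 of 750. In knockout 2, 1 count is 29.5 normalized counts, so every gene met the cut of 20 there. A gene that otherwise reached 20 only in the other knockout tumors could therefore be kept. Housekeeping genes and controls were not tested. Log2(value + 1) was fitted with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3, knockout against wild type, without covariates, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The added 1 shrinks the fold change of weak genes, while values of knockout 2 below its background can raise or lower it. A list score is the mean log2 value over the tested members. Group means of scores were compared by a two-sided exact permutation test, whose smallest p is 0.00794 for 5 against 5 tumors, and adjusted over the 16 lists with at least 4 tested members. In all, 26 lists were fixed before the data were examined. The matching of symbols ignored case. Camera and fry in limma were run as alternatives; camera compares a list with the other genes tested. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

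Because more than 30 genes passed, the genes named are the 15 that rose and the 15 that fell the most among those past the threshold (only 1 fell), the 3 members with the smallest p of each fixed list, and the housekeeping genes as a check. This gave 69 genes, of which 1 is not reported here. Outside these, the fixed-list members Cd8a and Foxp3 are used for another form of the balance of effectors to regulatory T cells. Any further gene is named after its value was seen, and the text says so.

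The test was checked on 5 simulated tables with 200 genes changed in each, up or down with equal chance. Gene means came from the wild-type libraries other than wild type 1, and depth and spread from all libraries. Over 324 to 340 genes kept, limma recovered 92.1% of 4-fold and 52.7% of 2-fold changes, and called 0.49% of unchanged genes. On the same tables edgeR 4.0.16 recovered 95.2% and 55.4% and called 0.65%. A 2-fold change can therefore be missed at this size. No probe background was added and no one-sided shift was drawn. The rates for unchanged genes therefore do not cover false calls from background in a shallow library such as knockout 2.

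Alternatives chosen before the data were examined were TMM and total-count scaling, other filters and pseudocounts, a floor of 20, array weights, an exact rank test, the submitters' sample number as a covariate, a replicate block, each tumor left out, and other list statistics. Alternatives chosen after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered counts, and edgeR without knockout 2. Also chosen then were limma without knockout 2 with the filter applied again and a fit without the 3 libraries of fewest counts. Counts thinned to one depth and a filter on the background were added then too. The limma fit without knockout 2 under the first filter belongs to the fits chosen before.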

Results

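Transcripts of immune and cancer genes were counted in subcutaneous tumors grown in C57BL/6 mice from B16F10 cells, a mouse melanoma line. The injected cells either lacked SSBP4 (knockout, 5 tumors) or kept it (wild type, 5 tumors), and the tumors were harvested on day 15. The readout was an nCounter panel, which counts each transcript with a barcoded probe and without amplification, so a tumor's value sums over tumor cells and host cells. The panel gave 750 endogenous genes and 20 housekeeping genes. The Ssbp4 transcript is not among the genes analysed here, so the knockout itself could not be checked from these values. Values below are normalized counts, scaled by the authors to the housekeeping genes.

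Depth differed widely between the tumors. The whole counts recovered from the values summed to between 79124 and 497599 in wild-type libraries and between 11244 and 517427 in knockout libraries. The library with 11244 counts is knockout 2, where 1 count corresponds to 29.5 normalized counts. The background set by the negative-control probes was 266.5 normalized counts in knockout 2 and between 4.7 and 15.8 in the other 9 libraries. In knockout 2, 167 of 770 genes lay above background, against 382 to 598 in the other libraries. Weak genes therefore carry background in knockout 2, and gene counts, list scores and the leading folds are also given without it. Other folds include knockout 2 unless stated, and some weak genes depend on it. Without it the fold went from 10.6 to 8.74 for Oas2, from 8.33 to 6.48 for Ncf4, from 7.08 to 5.45 for Vcam1 and from 3.77 to 2.79 for Lif. Other genes went the other way, such as Fcer1g from 4.22 to 6.05.

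**Figure D1:**
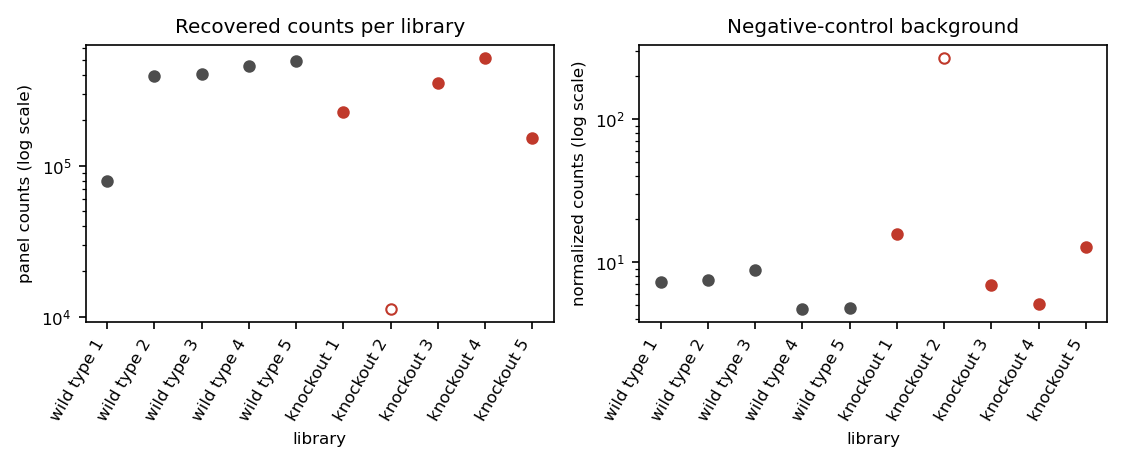
Recovered panel counts (left) and the negative-control background in normalized counts (right) for each library, both on log axes, with 1 point per tumor. Knockout 2 (open symbol) had 11244 counts and a background of 266.5, while the other 9 backgrounds lay between 4.7 and 15.8.

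The comparison of knockout with wild-type tumors asked how the loss of SSBP4 in the cancer cells alters the expression of immune genes in the tumor. Of 403 genes tested, 172 were higher and 1 was lower in knockout tumors (limma, Benjamini-Hochberg adjusted p under 0.05, n = 5 per group). Complement component C3 showed the largest rise, from 9.89 ± 7.62 (SD, n = 5) to 184 ± 113 (SD, n = 5) normalized counts, 15.3-fold on the log2(value + 1) scale (adjusted p = 0.00333), or 22.5-fold without knockout 2. The nucleic acid sensor Zbp1 rose 14.5-fold, the MHC class II chain H2-Eb1 13.9-fold and the immunoproteasome subunit Psmb9 13.1-fold; without knockout 2 these folds were 20.7, 17.0 and 12.4. Knockout 5 carried much of these 3 rises, which were 7.72-fold, 8.78-fold and 8.53-fold without it (limma adjusted p = 0.0222, 0.00472 and 0.00826). Knockout 1, at 22.1 for Zbp1 and 27.9 for Psmb9, lay within the wild-type range, and without it these 2 folds were 26.2 and 22.7. The adjusted p of Zbp1 reached 0.0479 without wild type 2. The calgranulin S100a8, the coagulation factor chain F13a1, the chemokine Cxcl14 and the complement protease Cfd rose between 11.2-fold and 11.9-fold. H2-Aa, Fcgr4, Ccr2, Oas2, Ly86 and Serpinb2 rose 10.3-fold to 11.2-fold. Without knockout 5 Fcgr4 rose 7.07-fold and H2-Aa 6.28-fold, and without wild type 5 Cxcl14 rose 19.98-fold. Of the 173 changed genes, 20 had a fold that moved by over 1.5 times on leaving out some 1 tumor. Hmgb1, a chromatin protein that also acts as an alarm signal, was the 1 lower gene, at 1751 ± 453 (SD, n = 5) against 2464 ± 298 (SD, n = 5) normalized counts, and fell by 0.53 on the log2 scale (SE 0.19, adjusted p = 0.0438). Its call was lost on leaving out 1 tumor in 6 of 10 cases (limma adjusted p up to 0.0995), though not without knockout 2 (adjusted p = 0.0291). Without knockout 2, 177 genes were higher and 1 was lower, and 162 of the 172 genes were again among the higher ones. Every gene met the filter on low values in knockout 2, through background alone if need be. With this filter applied again to the other 9 libraries, 141 of 367 tested genes were higher and 1 was lower. Among these higher genes were 127 of the 172. With a filter on background in place of the filter on low values, 258 of 536 tested genes were higher and 1 was lower. In wild-type tumors several of these genes were close to background: C3 and Serpinb2 lay above it in 2 of 5.

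The share of higher genes depended on the scaling. With TMM scaling over the panel genes, 122 genes were higher and 81 were lower, or 134 and 82 without knockout 2. The median log2 difference of all 403 genes was 0.63 with the authors' housekeeping scaling, 0.39 with scaling to total panel counts and 0.16 with TMM. Each list score below is therefore also given relative to the panel median of 0.63. This sets a mean over list members against a median over genes. Against the mean of the other genes tested every list stood lower, for example at 1.71 for macrophages and -0.187 for Toll-like genes. Of the score differences without knockout 2, all have an exact permutation p = 0.0159 (adjusted p = 0.0195) unless another p is given. All 16 lists tested had a higher mean score in knockout tumors, and 15 passed the threshold, as 15 did without knockout 2 and 11 with TMM or total-count scaling. Against the other panel genes, camera called 3 lists with a preset correlation and 0 with an estimated correlation, where 0 had an unadjusted p under 0.05.

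**Figure D2:**
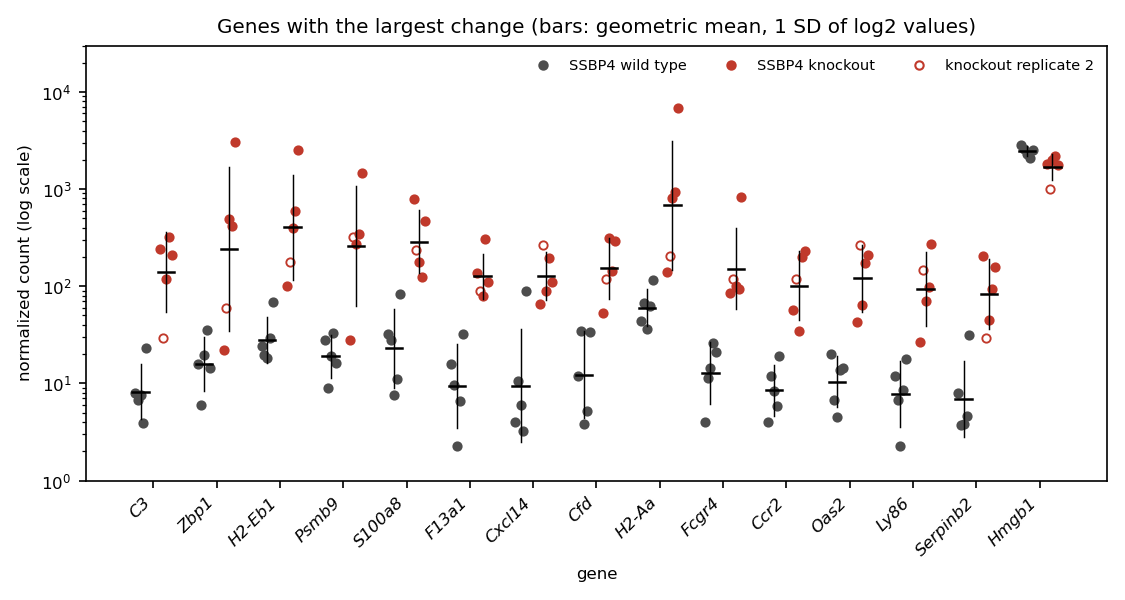
Normalized counts (log axis) of 14 genes with the largest rises and of Hmgb1, with 1 point per tumor, bars at the geometric mean and lines of 1 SD of the log2 values (n = 5 per group). C3 averaged 184 in knockout and 9.89 in wild-type tumors, and the open symbol marks knockout 2.

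Macrophage and monocyte genes rose together. Of 20 tested members, 19 were higher in knockout tumors, and all 20 when adjusted over the list alone; 4 of the 20 also belong to another list. Cd68, a lysosomal protein of macrophages, went from 115 ± 39.3 (SD, n = 5) to 411 ± 147 (SD, n = 5) normalized counts (log2 difference 1.83, SE 0.28, adjusted p = 0.00333). The monocyte chemokine receptor Ccr2 rose 10.7-fold and the anaphylatoxin receptor C3ar1 6.98-fold. Mertk, named after its value was seen as the 1 member that missed the threshold, had a log2 difference of 0.96 (adjusted p = 0.0502). The list score was 7.13 ± 0.62 in knockout and 4.47 ± 0.88 in wild-type tumors (mean log2 value ± SD, n = 5). The difference was 2.66, or 2.04 above the panel median (two-sided exact permutation p = 0.00794, adjusted p = 0.00977). Knockout 1, 3, 4 and 5 lay above all wild-type tumors; in knockout 2 only 1 of the 23 members measured lay above background, so its score is mostly background. Without knockout 2 the difference was 2.76 (exact permutation p = 0.0159, the smallest 4 against 5 tumors allow). Against the other panel genes, camera gave an adjusted p = 5.76e-05 with a preset correlation and an adjusted p = 0.598 with an estimated correlation.

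Other myeloid lists had too few tested members for a score. The neutrophil members S100a8, Ncf4 and Il1b were all higher, by 11.9-fold, 8.33-fold and 7.67-fold, as they were adjusted over the list alone. The dendritic cell members tested, Cd83, Clec4n and Cd1d1, were higher by 5.40-fold, 4.99-fold and 2.14-fold, also adjusted over the list alone. Without knockout 2, Cd1d1 no longer passed (adjusted p = 0.0899), nor did it with TMM scaling (adjusted p = 0.24). Fcer1g, a signaling chain of Fc receptors and the only tested mast cell and basophil member, rose 4.22-fold, a call lost on leaving out 1 tumor in 4 of 10 cases (limma adjusted p up to 0.0649).

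Genes induced by type I interferon rose in 16 of 21 tested members, with 16 also adjusted over the list alone, and in 19 without knockout 2. Rsad2, an antiviral enzyme, went from 80.3 ± 20.04 (SD, n = 5) to 484 ± 226 (SD, n = 5) normalized counts (log2 difference 2.46, SE 0.34, adjusted p = 0.00333). The transcription factor Irf7 rose 9.13-fold and the ubiquitin-like modifier Isg15 6.64-fold. The list score was 2.01 higher in knockout tumors, or 1.38 above the panel median (exact permutation p = 0.00794, adjusted p = 0.00977), and 2.16 higher without knockout 2. Camera gave an adjusted p = 0.00745 with a preset correlation and an adjusted p = 0.598 with an estimated correlation. Of 11 tested members of the interferon gamma list, 7 were higher, also when adjusted over the list alone; 5 of the 11 belong to another list. They included Psmb9, the transcription factor Irf8 (6.79-fold) and the adhesion molecule Icam1 (5.00-fold). This score was 1.79 higher, 1.16 above the panel median (exact permutation p = 0.00794, adjusted p = 0.00977; camera adjusted p = 0.666 with an estimated correlation), and 1.96 higher without knockout 2.

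Antigen presentation genes showed the widest spread among knockout tumors. For MHC class II, 5 of 6 tested members were higher, and 6 adjusted over the list alone. H2-Aa averaged 1781 ± 2847 (SD, n = 5) against 65.1 ± 30.7 (SD, n = 5) normalized counts, and H2-Dma rose 7.85-fold. Without knockout 5 the folds of H2-Aa and H2-Dma were 6.28 and 4.43. The class II score differed by 3.09, 2.47 above the panel median (exact permutation p = 0.00794, adjusted p = 0.00977; camera adjusted p = 0.598 with an estimated correlation), and by 3.60 without knockout 2. Without knockout 5 it differed by 2.30 (exact permutation p = 0.0159). It was 5.96, 8.21, 8.75 and 11.2 in knockout 1, 3, 4 and 5 and at most 5.60 in wild-type tumors. In knockout 2, 0 of the 10 class II members measured lay above background, so its score of 5.98 is a background value. For MHC class I, 8 of 10 tested members were higher, and 10 adjusted over the list alone. They included the immunoproteasome subunit Psmb8 (7.89-fold) and the class I-like molecule H2-M3 (5.26-fold). Psmb8 rose 4.88-fold without knockout 5 and 13.1-fold without knockout 1. The class I score differed by 2.32, 1.69 above the panel median (exact permutation p = 0.0159, adjusted p = 0.0169; camera adjusted p = 0.598 with an estimated correlation). Without knockout 2 it differed by 2.62 (exact permutation p = 0.0317, adjusted p = 0.0339). Knockout 3, 4 and 5 lay above all wild-type tumors, and knockout 1, at 6.54, lay within their range. In knockout 2, 3 of the 14 class I members measured lay above background.

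**Figure D3:**
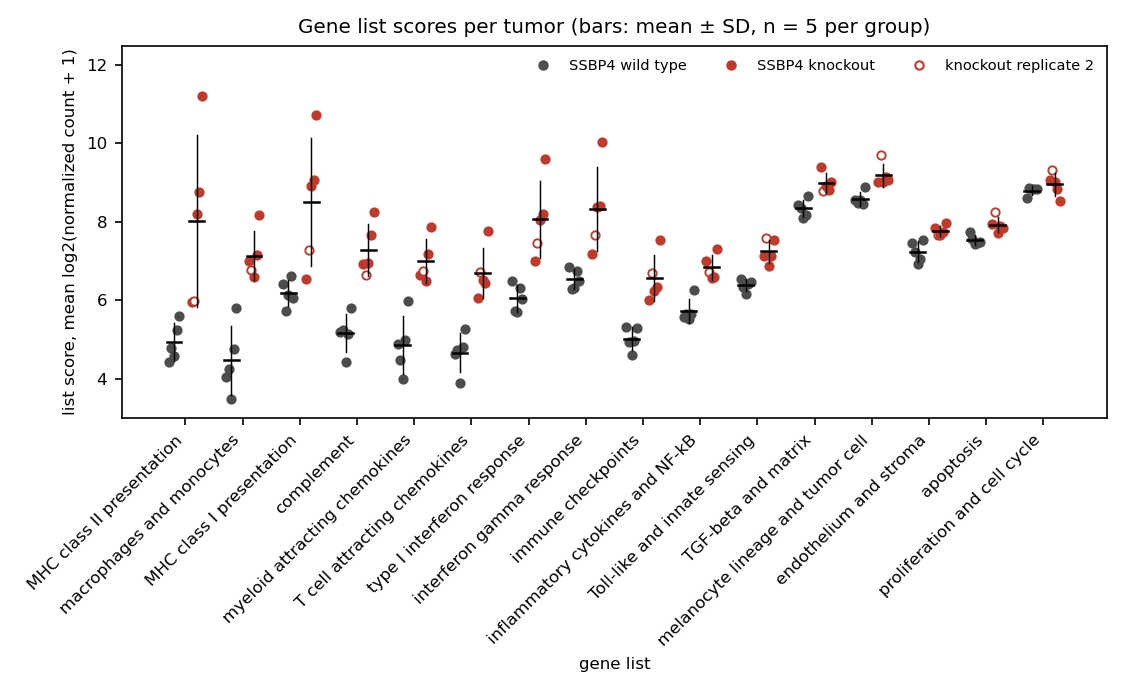
Scores of the 16 tested gene lists in each tumor, as the mean log2(normalized count + 1) of the tested members, with 1 point per tumor and bars at the mean ± SD (n = 5 per group). The macrophage score was 7.13 in knockout and 4.47 in wild-type tumors, and the proliferation scores of the groups overlapped; with TMM scaling the proliferation difference turned from 0.16 to -0.32, and the apoptosis difference from 0.39 to -0.08.

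Chemokine lists rose as well. Of 11 tested myeloid attracting chemokines 10 were higher, among them Ccl6 (6.37-fold), the eotaxin Ccl11 (5.85-fold) and Ccl3 (5.84-fold). Of 6 tested T cell attracting chemokines and receptors 5 were higher, among them Cxcl16 (6.16-fold) and Ccl21a (5.99-fold). Both counts were the same adjusted over the list alone. The scores differed by 2.12 and 2.04, 1.5 and 1.41 above the panel median (exact permutation p = 0.00794 for each, adjusted p = 0.00977; camera adjusted p = 0.598 with an estimated correlation for each), and by 2.18 and 2.03 without knockout 2. Of 6 tested immune checkpoint members 4 were higher, and 5 adjusted over the list alone. They included the ligand receptor Tnfrsf14 (4.99-fold), the ectonucleotidase Entpd1 (4.53-fold) and Havcr2, which encodes TIM-3 (2.89-fold). The checkpoint score differed by 1.55, 0.92 above the panel median (exact permutation p = 0.00794, adjusted p = 0.00977; camera adjusted p = 0.598 with an estimated correlation), and by 1.52 without knockout 2.

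Complement genes rose in 13 of 15 tested members, as they did adjusted over the list alone. Serping1, the inhibitor of C1, went from 48.5 ± 15.97 (SD, n = 5) to 264 ± 113 (SD, n = 5) normalized counts (log2 difference 2.38, SE 0.34, adjusted p = 0.00333). The score differed by 2.13, 1.5 above the panel median (exact permutation p = 0.00794, adjusted p = 0.00977), and by 2.29 without knockout 2. Camera gave an adjusted p = 0.00745 with a preset correlation and an adjusted p = 0.598 with an estimated correlation. Inflammatory cytokine and NF-kB genes were higher in 7 of 14 members, among them Il1b, Lif (3.77-fold) and Il18 (2.13-fold). Il18 lost its call with TMM scaling (adjusted p = 0.146) and without 1 tumor in 3 of 10 cases (limma adjusted p up to 0.0616). Toll-like and innate sensing genes were higher in 8 of 19 members, among them Casp1 (7.96-fold), Tlr8 (6.92-fold) and Nod1 (4.61-fold). Both counts were the same adjusted over the list alone. Their scores differed by 1.11 and 0.86 (exact permutation p = 0.00794 for each, adjusted p = 0.00977). These differences were 0.485 and 0.237 above the panel median, and the differences without knockout 2 were 1.14 and 0.78. Against the mean of the other genes tested they were 0.0729 and -0.187, so neither list clearly exceeded the panel. With an estimated correlation, camera gave adjusted p = 0.598 for the first and adjusted p = 0.8997 for the second.

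Lists of matrix, vessel, tumor cell and cell division genes moved less. Of 16 tested TGF-beta and matrix members 7 were higher, also adjusted over the list alone. The collagen Col3a1 went from 263 ± 156 (SD, n = 5) to 1052 ± 434 (SD, n = 5) normalized counts (adjusted p = 0.00515). Tgfb1 and Tgfbr2 were 1.65-fold and 1.43-fold higher, and both lost the call with TMM scaling (adjusted p = 0.18 and 0.878). Of 13 tested endothelium and stroma members 2 were higher, also adjusted over the list alone. These were the adhesion molecule Vcam1 (7.08-fold) and the chemokine Cxcl12 (3.42-fold), while the endothelial Vwf averaged 310 against 206 normalized counts (adjusted p = 0.0999), and was past the threshold without knockout 2 (adjusted p = 0.0382). The call of Cxcl12 was lost on leaving out 1 tumor in 4 of 10 cases (limma adjusted p up to 0.0575). Of 5 tested members of the melanocyte and tumor cell list only the cadherin Cdh1, an adhesion molecule of epithelial cells, was higher (5.65-fold), also adjusted over the list alone; Mcam and Kit had log2 differences of 0.36 and 0.17 (adjusted p = 0.197 and 0.838). The apoptosis members Fas and Bcl2l1 were higher among 10 tested, 1 of them adjusted over the list alone. Without knockout 2, Bcl2l1 no longer passed (adjusted p = 0.0596), nor did it with TMM scaling (log2 difference 0.34 against 0.82, adjusted p = 0.372).

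The matrix, endothelium and tumor cell scores differed by 0.64, 0.53 and 0.61 (exact permutation p = 0.00794 for each, adjusted p = 0.00977), and the apoptosis score by 0.39 (exact permutation p = 0.0159, adjusted p = 0.0169). Relative to the panel median these were 0.0137, -0.102, -0.021 and -0.234, and without knockout 2 the differences were 0.69, 0.55, 0.48 and 0.31 (exact permutation p = 0.0317 for apoptosis). With TMM scaling all 4 calls were lost, at 0.16, 0.05, 0.13 and -0.08 (exact permutation, adjusted p = 0.469 for the first and 0.595 for the others). With an estimated correlation, camera gave adjusted p = 0.783 for the matrix list and adjusted p = 0.598 for the other 3. None of 6 tested proliferation members passed in limma, and none had an unadjusted p under 0.05; edgeR on the recovered counts also called none. Birc5, Trp53 and Cdk1 had log2 differences of -0.27, 0.23 and 0.62. With TMM scaling Birc5, an inhibitor of apoptosis needed for cell division, was lower in knockout tumors, at -0.75 (limma adjusted p = 0.00693). The proliferation score differed by 0.16, -0.469 relative to the panel median, and by 0.066 without knockout 2 (exact permutation p = 0.302 with all tumors and 0.603 without it).

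Lymphocyte genes were mostly too weak to test. The T cell list kept 3 of 19 members, the cytotoxic, regulatory T cell and B cell lists 1 each and the NK cell list 0 of 20. Thy1, also found on stromal cells, rose 2.24-fold (adjusted p = 0.0428), but not past the threshold without knockout 2 (adjusted p = 0.0884), with TMM scaling (adjusted p = 0.145) or when adjusted over the list alone. Lck and Tcf7 had log2 differences of 0.60 and -0.11 (adjusted p = 0.256 and 0.891). The chemokine Ccl5 rose 4.16-fold (adjusted p = 0.0379) and Cd37 2.42-fold (adjusted p = 0.0327). Ccl5 lost its call on leaving out 1 tumor in 7 of 10 cases (limma adjusted p up to 0.0887). With TMM scaling the adjusted p of Ccl5 and Cd37 were 0.0617 and 0.125, and Cd37 had an adjusted p = 0.0614 without knockout 2. The lymph node list kept Ccl21a alone. The costimulation members Icosl and Tnfrsf9 had log2 differences of 0.51 and 0.64 (adjusted p = 0.237 and 0.267). A median of 12 T cell members lay above background in the 4 knockout libraries other than knockout 2, and a median of 5 in wild-type libraries. For cytotoxic effectors the medians were 8.5 and 2 of 17 members. In wild type 1, where background was 7.3 normalized counts or about 2 counts, 11 T cell and 6 cytotoxic members lay above it.

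The balance of cytotoxic effectors to regulatory T cells rested on Ccl5 and Ikzf2, the only members of each list that were tested. With 1 gene on each side, it cannot be read as a balance of the cell types. The difference of Ccl5 and Ikzf2 was 1.31 higher in knockout tumors on the log2 scale, and no group difference was detected with 5 tumors per group (exact permutation p = 0.238). In knockout 2 both genes lay below background, and without it the difference was 1.91 (exact permutation p = 0.0794). It was 0.716 without knockout 5 and 0.724 without wild type 1 (exact permutation p = 0.476 and 0.460). Ikzf2 had a log2 difference of 0.75 (adjusted p = 0.142). It lay above background in 5 of 5 wild-type tumors, while the regulatory T cell gene Foxp3 did so in 0. The difference of Cd8a and Foxp3, which lay above background in 1 and 0 of the 9 libraries other than knockout 2, was 1.02 (exact permutation p = 0.206).

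The 20 housekeeping genes had log2 differences between -0.37 and 0.26. None passed the threshold in limma or in edgeR, and 2 had an unadjusted p under 0.05. The scaling sets their geometric mean to the same value in every library, so their average cannot differ between the groups. These values therefore do not show whether the housekeeping reference is stable. Across the tested genes, the Spearman correlation between libraries was 0.94 to 0.98 within wild type and 0.57 to 0.96 within knockout, or 0.67 to 0.96 without knockout 2. Between the groups it was 0.61 to 0.94, which overlaps the range within knockout. Knockout 1 stood closer to the wild-type tumors (0.871 to 0.942) than to the other knockout tumors (0.673 to 0.858). These correlations run across genes, which are not independent replicates.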

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

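Chosen after values had been seen were the thinning of counts, the differences between list scores, the search among genes not tested, the positive-control comparison, and the use of TMM scaling and of the fit without knockout 2 as tests of explanations; both of these settings had been chosen before.

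Of 174 groups of 5 tumors examined, 13 held a tumor far from the others, and chance gives about 1 in 20. Among libraries, wild type 1 had a low total of 79124 recovered counts, and the positive-control totals of knockout 5 (6375) and wild type 1 (7441) lay far below the others of their groups. Wild type 5 had the highest inflammatory cytokine score of its group (6.27) and the highest melanocyte and tumor cell score (8.88). Wild type 1 had the lowest proliferation score (8.61). Knockout 2 had the highest melanocyte and tumor cell score of its group (9.70), the lowest Hmgb1 (1003 normalized counts), and the highest Ikzf2 (236), Lif (147.5) and Tgfbr2 (619.5). Of these, Ikzf2 and Lif lie below that library's background of 266.5. Knockout 5 had the highest Fcgr4 (827.8), and wild type 1 the highest Tgfbr2 of its group (395.9).

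Among the 347 genes not tested, 15 lay above background in at least 3 of the 4 knockout libraries other than knockout 2 and in no wild-type library; 0 genes showed the reverse. They include the cytotoxic genes Gzmb, Prf1 and Klrk1 and the T cell genes Cd3e and Zap70, named here after their values were seen. Gzmb was 5.88, 11.6, 8.49 and 107.7 normalized counts in knockout 1, 3, 4 and 5, and at most 4 in wild-type tumors. The difference was not tested.

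The first pattern is the one-sided rise of 172 genes. Depth as its whole cause is argued against, because 151 genes were higher after knockout 2 was left out and the counts of the other 9 libraries were thinned to one depth. Scaling alone is argued against for the macrophage rise, since the macrophage minus proliferation score, which no scaling changes much, was 2.51 higher in knockout tumors (exact permutation p = 0.00794), or 2.69 without knockout 2. For the near absence of lower genes scaling stays open and cannot be told apart from a true shift: TMM gave 81 lower genes, and the data do not show which reference is stable. Fewer tumor cells with all host cells up alike is argued against only if the endothelium and stroma list reads host cells. The macrophage minus endothelium and stroma score, chosen after both scores were seen, was 2.14 higher (exact permutation p = 0.00794), or 2.20 without knockout 2. The endothelium list shares Mcam with the tumor cell list, and bulk values do not show which cells express its other members. Of its 13 tested members 2, Vcam1 and Cxcl12, were higher. Of 16 tested TGF-beta and matrix members 7 were higher, among them Col3a1 by 4.17-fold. Fewer tumor cells with host cell types up unequally stays open. Chance is argued against by 100 splits of the 10 tumors, of which only the real 1 gave as many as 173 genes (the next gave 18). For the macrophage part, a hypothesis that was not tested is more myeloid cells or a higher expression of their genes in tumors without SSBP4, which bulk values do not separate. For the interferon, antigen presentation and other genes no biological explanation was tested, and expression by the tumor cells stays open.

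The second pattern is the spread of the MHC class II score, over 5.24 log2 units among the 4 knockout tumors other than knockout 2. Depth is argued against, because the range was 5.12 after thinning. The macrophage score ran only from 6.58 to 8.18 in these tumors. The range of the class II minus macrophage score, 4.05, was therefore bound to stay wide. Macrophage content alone is argued against only if class II genes change in proportion to the macrophage score, and a steeper relation was not tested. A different interferon response from tumor to tumor may be involved, which was not tested.

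The third pattern is the low count of knockout 2. A failed hybridization or scan is argued against by its positive-control total of 24634, while the lowest of the other libraries had 6375. Most gene calls do not rest on it, since 162 of the 172 higher genes were higher without it under the first filter. With the filter also applied again without knockout 2, 127 of the 172 were higher. Low or degraded RNA input stays open, as no measure of either is among the values, and no biological explanation was tested.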

How the results depend on the processing

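The edgeR, DESeq2, thinning, background-filter and 3-library settings were chosen after seeing the data. Leaving out 1 tumor at a time gave 132 to 178 changed genes, 15 to 16 lists and a balance difference of 0.716 to 1.91. Of 57 called named genes, 9 lost the call without some tumor and none changed sign: Bcl2l1, Ccl5, Cd1d1, Cd37, Cxcl12, Fcer1g, Hmgb1, Il18 and Thy1, with adjusted p up to 0.121. For 13 of the 15 called lists leaving out 1 tumor says nothing about stability, since their groups do not overlap and p is then always the smallest possible; MHC class I and apoptosis kept the call without each tumor. The count of changed genes was 275 with no filter (750 genes tested) and 23 with at least 50 in all libraries (236 tested). Counts were 203 with TMM (122 higher, 81 lower), 155 with total counts (138 higher, 17 lower), 182 with edgeR and 234 with DESeq2 (136 higher, 98 lower). They were 152 with knockout 2 left out and the others thinned, and 135 without the 3 shallowest libraries. Tgfbr2 turned to -0.0876 with DESeq2; the cause was not tested. Lists past the threshold numbered 7 of 9 with at least 50 in all libraries, 11 of 16 with TMM, 3 with camera's preset correlation and 0 with its estimated correlation, where 0 had an unadjusted p under 0.05; fry called 15. They were 0 without the 3 shallowest libraries, where the smallest exact p is 0.0571. The apoptosis score turned to -0.0832 with TMM, and the melanocyte score to -0.0434 as a median of members; the cause was not tested. Relative to other genes, as camera tests it, 6 lists turned negative with either correlation: Toll-like -0.187, matrix -0.418, endothelium -0.534, melanocyte -0.441, apoptosis -0.665 and proliferation -0.897 (log2). Housekeeping scaling applied again is identical to the main values and was not run separately. Birc5 became a lower gene with TMM and total-count scaling. Of each lymphocyte list at most 3 members were tested.

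Same-numbered tumors deviated together with correlations of 0.05, 0.15, 0.31, 0.28 and 0.24, all of them positive. Knockout 3 and 4 correlated best with their own number, and knockout 1, 2 and 5 with another. The labels name no pairs, and these values do not settle whether same-numbered tumors share more than a number. With the number as a replicate block 171 genes passed, all of them higher, so Hmgb1 lost its call. It also lost its call with the submitters' sample number as a covariate, where 182 genes were higher and 0 lower. The paired sign-flip test over 5 pairs called 0 lists, since its smallest p is 0.0625, and the balance difference stayed at 1.31 (exact permutation p = 0.25).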

Other observations

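Of the 172 higher genes, 60 belong to no fixed list; those named here were chosen after their values were seen. Ptprc, the pan-leukocyte antigen CD45, was 71.6 ± 54.0 (SD, n = 5) normalized counts in knockout and 8.49 ± 5.56 (SD, n = 5) in wild-type tumors (limma adjusted p = 0.00424). Cybb, the phagocyte oxidase subunit, rose 8.51-fold (adjusted p = 0.00356). The receptor tyrosine kinases Axl and Egfr had log2 differences of 2.08 and 2.38 (adjusted p = 0.00356 and 0.00333).

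Cxcl9, a chemokine induced by interferon gamma and not tested because of low values, was 5.88, 244.8, 168.5 and 1168 normalized counts in knockout 1, 3, 4 and 5. In wild-type tumors it was 3.74 to 19.6. It was chosen after its values were seen.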
